A study of Xanthoceras sorbifolium with 9 samples.

How the data were processed

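Poly(A) RNA of top leaves was sequenced on an Illumina HiSeq instrument, per the labels' protocols, in 3 libraries for each of 3 groups that received 2, 0.2 or 0 mmol/l ammonium nitrate for 15 days. Groups were taken from the sample titles. The authors deposited 3 tables of comparisons over the same 242816 assembled features. Per the file headers, each table gives the mean TPM of 2 groups (a share of the library that does not keep its depth), a log2 fold change, a p-value, a q-value, a call and matches to public sequence and protein databases. The aligner, the quantification tool and the statistical model are not given in the sources used here; the submitters' processing notes name the mouse builds GRCm38 and mm10, while the features carry assembly identifiers and no genome positions. No depth per library is known.

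What the tables hold was tested on them. The log2 fold change in the deposited tables equals the log2 ratio of the 2 mean TPM values to within 0.0021, with 0.0001 in place of 0. At that floor lay 36659 features in CK, 84017 in LN and 62735 in NN. The third table is the NN comparison mirrored, with the same fold changes. The call of the authors follows an unadjusted p-value below 0.05 with a log2 fold change of at least 1 in size, with 0 exceptions. The deposited q-values fit an adjustment over about 29300 features in the LN table and about 233400 in the NN table, so a q is stricter in NN and counts at q are not comparable between the comparisons.

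The design fixed before the data were examined assumed values per library, with count models, gene set tests, left-out replicates, a replicate block and other splits of the samples. The tables give group means, so none of these was run, and the fallback fixed with that design was used: no test of its own, and the authors' deposited comparison at q below 0.05. LN and NN were compared by ratios of means without a test.

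Each feature was assigned to an organism group by the first word of its nucleotide database match, or of its green-plant protein match where it had none. The Sapindales-matched features of at least 1 TPM in 1 group served as the reference for gene lists. This reference was chosen after seeing the data, in 2 steps: Sapindales with other flowering plants came first, and the latter were left out when their photosystem members were seen to move with features of other organisms. The 37 gene lists, fixed before the data were examined, were matched to Swiss-Prot descriptions, or to protein database descriptions where there was none, among plant-matched features of at least 1 TPM. For each list the deposited p-values were also adjusted by the Benjamini-Hochberg method over the list alone. The median log2 ratio of its Sapindales-matched members was set against 10000 random lists with the same number of genes in each of 10 bins of mean TPM (2000 under each alternative). This describes these group means and is not a test across libraries. With 37 lists, about 5% would lie outside the central 95% by chance if genes moved independently. Genes of one list can move together, which the random lists do not allow for, so more may lie outside without any effect of nitrogen. In LN 15 of the 37 lists lay outside that range, 9 above and 6 below, in NN 11 (4 and 7), and for NN over LN 11 (5 and 6).

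Genes were named by a rule fixed before the data were examined: the 5 highest and 5 lowest fold changes past q with at least 5 TPM in the higher group and a named plant protein, and from each list the member with the lowest p in each direction, or for the nitrogen lists without one the most abundant member. For the fold changes, features at the floor were left out and a plant nearest match was required. These conditions were not part of the rule fixed beforehand. The rule's condition that libraries do not overlap could not be evaluated from group means. Only 3 fallen genes met the rule with these additions in LN.

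The steps were tested on simulated data for LN against CK over 12437 features. On independent normal scores with a large shift in the changed genes, the adjustment recovered 97% of changed genes, with 3% of its calls unchanged genes. This checks the arithmetic and does not give the error rates of the authors' comparisons. With fold changes shuffled among genes, 2% of 100 simulated lists of 30 genes without a shift lay outside the central range. With a log2 shift of 0.25, 95% did. The shuffle removes any movement that genes of a list share. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.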

Results

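RNA was sequenced from the youngest leaves of yellowhorn (Xanthoceras sorbifolium, an oil-bearing tree of the soapberry family, order Sapindales) grown in sand and watered for 15 days with solutions that differed in their only nitrogen source. The control group, CK, received 2 mmol/l ammonium nitrate, the low-nitrogen group, LN, received 0.2 mmol/l, and the nitrogen-free group, NN, received 0 mmol/l. Each group had 3 libraries, 9 in all. The authors' tables give, for 242816 features of a transcriptome assembly, the mean TPM of each group and a comparison of LN and of NN with CK. They hold group means only, so the values below carry no spread between libraries and no depth. Genes are described as changed where the q-value in the authors' table is below 0.05. That threshold was set for this report, and the authors' own calls, which use an unadjusted p, are given apart. The assembly gives features without genome positions, and near-identical copies or fragments of one gene can share reads, so single features of a gene family are uncertain. Nothing in the labels says that the 3 libraries of a group came from separate plants, so the authors' p-values measure the spread between these libraries, which may be technical.

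The features did not all match plants. By the organism of each feature's nearest match, Sapindales held 29.04% of the summed mean TPM in CK, 39.3% in LN and 39.3% in NN, and other flowering plants held 19.2%, 24.01% and 23.6%. Features matched to mouse and other rodents held 10.5% of the TPM in CK, 3.47% in LN and 4.16% in NN, and those matched to human and other primates 1.80%, 0.637% and 0.839%. Bacterial matches held 3.64%, 2.73% and 2.75%, and matches to Arabidopsis and its relatives 11.96%, 8.49% and 9.30%. Nucleotide matches took precedence, so TRINITY_DN76104_c3_g3, with a bacterial nucleotide match but a plant protein match, is not counted as plant. It stood at 4803 TPM in CK, 9986 in LN and 9850 in NN. Among features of at least 1 TPM in a group, the 12437 matched to Sapindales had a median log2 ratio of 0.62 for LN over CK and 0.55 for NN over CK. Changes are read against these shifts. The 7296 matched to rodents had medians of -1.70 and -1.37. Gene groups are therefore described against the Sapindales median. A named gene's match to Arabidopsis and its relatives, legumes or grasses is stated. The other named genes matched Sapindales or other flowering plants. Relative to the same median, 150 of the 165 features that rose in LN and 89 of the 90 that rose in NN lay at least 2-fold higher.

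**Figure D1:**
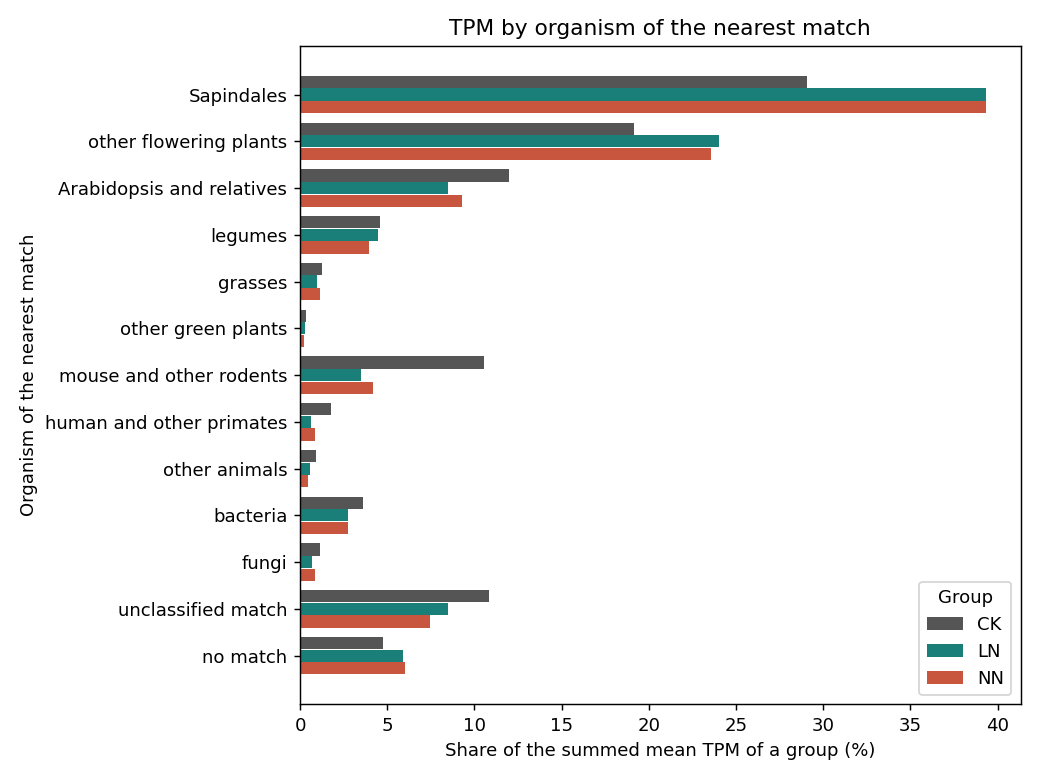
Share of the summed mean TPM (x axis, percent) held by features of each nearest-match organism (y axis) in CK, LN and NN, from the authors' group means, without error bars because the tables give none. Features matched to rodents held 10.5% in CK and 3.47% in LN, while those matched to Sapindales held 29.04% and 39.3%.

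The comparison of LN with CK asks which leaf genes responded to a reduced nitrogen supply. The risen genes included members of amino acid transport and breakdown, jasmonate synthesis, flavonoid and lignin synthesis and cell wall expansion. Allantoinase (TRINITY_DN74121_c0_g2), a purine-breakdown enzyme placed in the amino acid list by its description, rose from 42.8 TPM in CK to 208 in LN in the authors' deposited table (log2 fold change 2.28, q = 4.4e-05). Linoleate 13S-lipoxygenase 2-1, an enzyme at the start of jasmonate synthesis, rose from 22.96 to 103 TPM in the authors' deposited table (log2 fold change 2.16, q = 0.0010). Leucoanthocyanidin reductase, which makes flavan-3-ols, rose from 2.44 to 15.5 TPM and laccase-9, of a family of lignin-polymerising oxidases, from 3.27 to 27.0 TPM in the authors' deposited table (log2 fold changes 2.66 and 3.05). Among the fallen genes, cytosolic triosephosphate isomerase, a glycolytic enzyme, fell from 43.4 to 11.1 TPM in the authors' deposited table (log2 fold change -1.97, q = 0.022).

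The jasmonate list held 81 plant-matched features, of which 5 rose and none fell at the authors' q, and 16 rose when adjusted over the list alone. Flavonoid and anthocyanin synthesis had 3 risen of 72 (6 adjusted over the list alone), and the median of its 20 Sapindales-matched members was 1.02, above the 0.43 to 0.77 that held the central 95% of 10000 random lists matched on mean expression. Phenylpropanoid and lignin synthesis had 3 risen of 128 (6 adjusted over the list alone) and a median of 0.81, against 0.48 to 0.72 in random lists. The antioxidant list had 5 risen of 255 (6 adjusted over the list alone), led by a glutathione S-transferase that went from 152 to 497 TPM in the authors' deposited table. Its median of 0.74 lay above 0.47 to 0.64. Cell wall expansion had 5 risen of 260 (6 adjusted over the list alone), among them expansin-like B1, from 0.931 to 11.4 TPM in the authors' deposited table, but its median of 0.57 lay within 0.52 to 0.74. Amino acid transport and breakdown had 4 risen of 162, allantoinase with the lowest p, and 4 adjusted over the list alone; its median of 0.60 lay within 0.52 to 0.71. WRKY factors had 3 risen of 105 (5 adjusted over the list alone), and terpenoid and saponin synthesis 2 of 103 (6 adjusted over the list alone). Many of these risen members matched other plants: those matched to Sapindales were 1 of 5 in the jasmonate list, 1 of 3 in flavonoid synthesis, 3 of 3 in phenylpropanoids, 4 of 5 in antioxidants, 1 of 5 in cell wall expansion, 1 of 4 in the amino acid list, 1 of 3 in WRKY factors and 1 of 2 in terpenoids. Taken over all plant matches instead of Sapindales matches, 15 of the 37 list medians in LN had the opposite sign, among them the phenylpropanoid (-0.041), antioxidant (-0.41) and cell wall expansion (-0.19) lists.

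Several lists of photosynthesis and the plastid lay low in LN relative to other Sapindales-matched genes, but not all of their transcripts did. The low position was not particular to them. The phosphate starvation and auxin lists lay low as well, and the cytosolic ribosome list just below random lists (0.444 against 0.445 to 0.574). The 42 Sapindales-matched members of the photosystem and light-harvesting list had a median log2 ratio of 0.32, below the 0.45 to 0.63 of random lists, chlorophyll synthesis (21 members) had 0.31 against 0.42 to 0.69, and the plastid ribosome (39 members) 0.18 against 0.44 to 0.65. The top bin of mean TPM has no upper limit, so very abundant photosystem members are matched only loosely. The summed TPM of all Sapindales matches shifted by 0.44 in LN, less than their median of 0.62. That of these 42 members went from 27478 in CK to 35865 in LN. The Calvin cycle and photorespiration list (22 members) had 0.49, within 0.41 to 0.70, but lay below random lists when other flowering plants were included (0.12). A very abundant feature outside these lists (TRINITY_DN76104_c3_g3), chosen after its values were seen, with a protein match to a plant chlorophyll a-b binding protein and a nucleotide match to a bacterium, stood at 4803 TPM in CK and 9986 in LN in the authors' deposited table (q = 0.19). Over all plant matches the photosystem median was -0.72 and the plastid ribosome median -0.24. Chlorophyll synthesis then had 0.051, within the -0.064 to 0.47 of random lists. None of the Sapindales-matched members of these lists was called at the authors' q. In the whole plant-matched photosystem list of 328, 1 feature fell, chlorophyll a-b binding protein 6A (TRINITY_DN60101_c0_g1), from 9.90 to 0.0634 TPM in the authors' deposited table (q = 0.039), and 2 fell when adjusted over the list alone. That feature's nearest match lay outside Sapindales, as did all 21 photosystem features that the authors called lower, and features of other flowering plants in this list had a median of -0.93.

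Genes of nitrate and ammonium transport (43 Sapindales-matched features and others of plants), nitrogen assimilation (75 plant-matched features) and nitrogen signalling (33) had no member past the authors' q in LN, and none adjusted over the list alone. Their most abundant members were a high-affinity nitrate transporter 3.1 with 139 TPM in CK and 190 in LN, a cytosolic glutamine synthetase matched to Arabidopsis and its relatives with 1123 and 1800 TPM, and BTB/POZ and TAZ domain-containing protein 1 with 75.6 and 100 TPM in the authors' deposited table (q = 0.55, 0.34 and 0.53). Relative to the Sapindales median shift, their log2 ratios in LN were -0.17, 0.06 and -0.21. The Sapindales-matched medians of these lists, 0.53, 0.73 and 0.76, lay within random lists. Transport lay above them with other flowering plants included (0.74 against 0.50 to 0.69) and just below with TPM summed per Swiss-Prot entry (0.480 against 0.481 to 0.740). Assimilation lay above with TPM so summed (0.75 against 0.44 to 0.73) and below over all plant matches (-0.48 against -0.26 to 0.47). By fold change, the highest risen genes were feruloyl CoA ortho-hydroxylase 2 (TRINITY_DN75758_c2_g5), an enzyme of coumarin synthesis, and a chloroplast polyphenol oxidase, with log2 fold changes of 5.29 and 4.93 in the authors' deposited table. They were followed by an adenylylsulfatase of the FHIT family at 4.05, a cytochrome b5 at 3.79 and an aspartyl protease at 3.70 in the authors' deposited table. The hydroxylase feature stood at 0.887 TPM in CK. More abundant features of its assembly component, TRINITY_DN75758_c2_g1 and TRINITY_DN75758_c2_g2, stood at 13.7 and 10.4 TPM in CK. Their log2 fold changes in LN were 0.02 and -0.06 in the authors' deposited table. The cytochrome b5 passed q in NN as well, at 10.8 TPM in the authors' deposited table (q = 0.010). A feature matched to vacuolar protein sorting-associated protein 35A fell from 6.38 to 0.212 TPM in the authors' deposited table.

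In total 165 features rose and 155 fell at the authors' q in LN, a split that changed with the organism: 142 rose and 10 fell among plant matches, and 78 rose and 6 fell among Sapindales matches. The authors' own calls in the deposited table, at an unadjusted p below 0.05 and at least a 2-fold difference, numbered 2475 higher and 5636 lower, of which 3593 of the lower calls were matched to rodents.

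**Figure D2:**
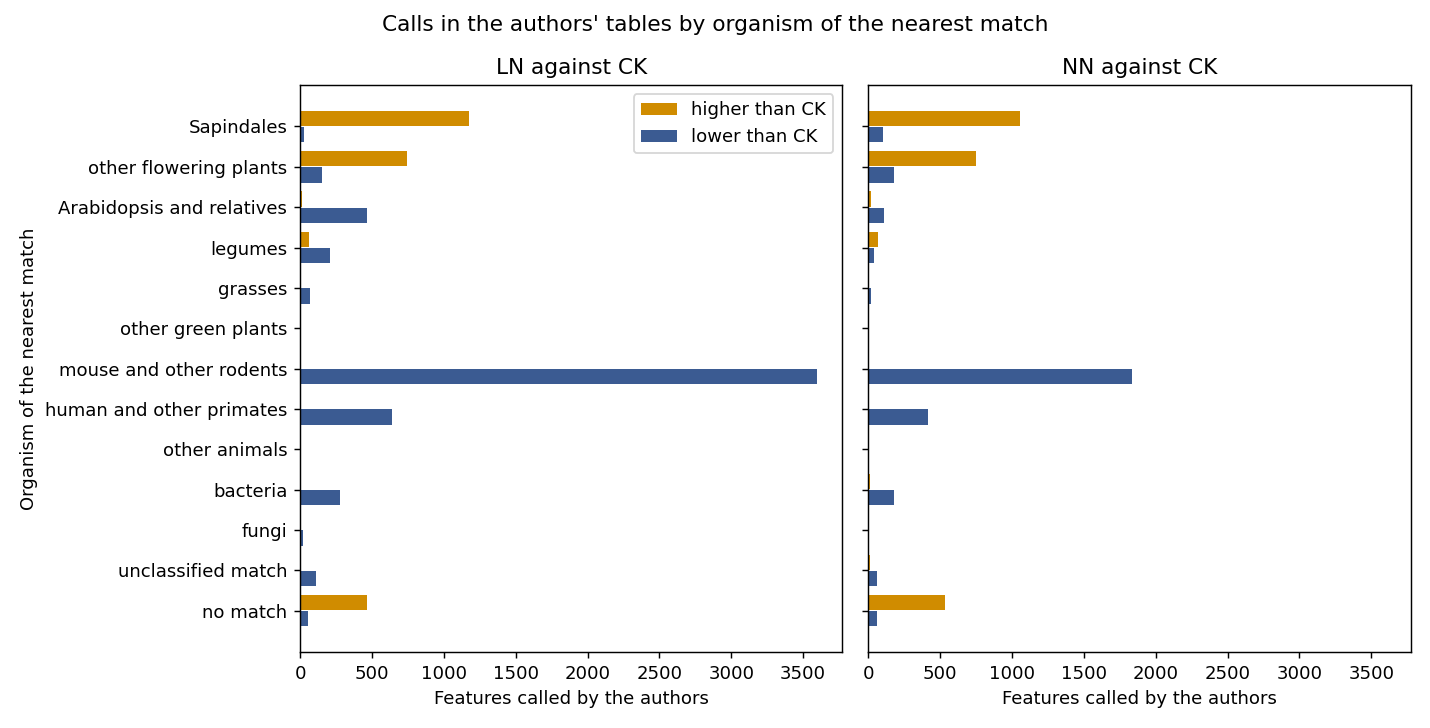
Number of features called higher or lower than CK in the authors' tables (x axis) by the organism of the nearest match (y axis), for LN (left) and NN (right). In LN, 3593 of the 5636 lower calls were matched to rodents, and Sapindales held 1179 higher and 26 lower calls.

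The comparison of NN with CK asks which genes responded to the absence of nitrogen. Glutamate dehydrogenase 1 (TRINITY_DN75583_c1_g1), which releases ammonium from glutamate, rose from 12.7 TPM in CK to 57.5 in NN in the authors' deposited table (log2 fold change 2.18, q = 0.0016). Allantoinase rose to 207 TPM, and oligopeptide transporter 7 went from 1.22 to 9.71 TPM in the authors' deposited table (log2 fold changes 2.27 and 2.99, q = 0.022 and 2.4e-06). Oligopeptide transporter 7 rose in LN as well, to 5.90 TPM in the authors' deposited table (log2 fold change 2.27, q = 3.3e-07). The jasmonate-list enzyme 12-oxophytodienoate reductase 2 rose from 61.9 to 400 TPM in the authors' deposited table (log2 fold change 2.69, q = 0.0017). Among the fallen genes were a cysteine proteinase 15A, matched to Arabidopsis and its relatives, from 514 to 21.3 TPM, an agglutinin, a carbohydrate-binding protein, from 25.7 to 0.985 TPM and pathogenesis-related protein PR-4B from 93.7 to 17.05 TPM in the authors' deposited table (q = 2.1e-12, 0.036 and 0.030). The agglutinin and PR-4B matched other flowering plants.

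Of the jasmonate list, 4 of 81 rose in NN and none fell, and 5 rose adjusted over the list alone; its Sapindales-matched median of 0.55 lay within the 0.37 to 0.72 of random lists. It lay above them when other flowering plants were included (0.85 against 0.36 to 0.64) and with TPM summed per Swiss-Prot entry (0.76 against 0.36 to 0.73). NAC factors had 2 risen of 59 (5 adjusted over the list alone), among them NAC domain-containing protein 2, from 8.42 to 29.7 TPM in the authors' deposited table. The antioxidant list had 2 risen of 255 (4 adjusted over the list alone), with the same glutathione S-transferase at 576 TPM in the authors' deposited table. Of the risen members, 1 of 4 in the jasmonate list, none in NAC factors and both antioxidant ones matched Sapindales. In amino acid transport and breakdown 1 rose and 1 fell of 162 (4 and 1 adjusted over the list alone); the fallen member was a WAT1-related protein, from 5.64 to 0.105 TPM in the authors' deposited table. One-member calls came from the ethylene list (ERF071, from 6.21 to 30.2 TPM), the auxin list (auxin efflux carrier component 5, from 6.72 to 30.2 TPM), the heat shock list (a chloroplast small heat shock protein, from 0.947 to 6.82 TPM) and the cytosolic ribosome list (60S ribosomal protein L21-1, matched to a grass, from 134 to 314 TPM) in the authors' deposited table. Adjusted over each list alone, 8, 5, 3 and 1 members of these lists rose and none fell. The Sapindales-matched median of the auxin list, however, lay just below random lists in NN (0.43 against 0.44 to 0.67). It did so in LN too (0.50 against 0.52 to 0.72). A putative cyclin-D6-1 of the cell cycle list fell from 4.08 to 0.328 TPM and fasciclin-like arabinogalactan protein 8 of the cell wall list, matched to Arabidopsis and its relatives, from 10.3 to 2.75 TPM in the authors' deposited table. Adjusted over the list alone, 3 rose and 1 fell in the cell cycle list, and 1 rose and 3 fell in the cell wall list.

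Cuticle and wax genes, which mark the epidermis, lay low in NN: the 17 Sapindales-matched members had a median log2 ratio of -0.06 while random lists lay between 0.34 and 0.75. None of these 17 passed the authors' q. Defence proteins (33 members) had a median of 0.27 against 0.38 to 0.73, cell wall expansion (57 members) 0.34 against 0.42 to 0.67, and the plastid ribosome 0.17 against 0.38 to 0.63; over all plant matches these medians were -0.27, -0.30 and -0.14. Higher than random lists were chlorophyll breakdown and leaf senescence (17 members, 0.76 against 0.35 to 0.74), ethylene (31 members, 0.74 against 0.39 to 0.72) and WRKY factors (52 members, 0.73 against 0.43 to 0.68), although ethylene had 1 risen plant-matched feature of 164 and the other lists none at the authors' q. None of the 4 lists above random lists in NN stayed above them with TPM summed per Swiss-Prot entry, and 1 did with a pseudocount of 1, chlorophyll breakdown and leaf senescence. Nitrogen assimilation had 1 risen member, glutamate dehydrogenase 1, while nitrate and ammonium transport and nitrogen signalling had none at q and 2 and 0 adjusted over the list alone. The nitrate transporter 3.1 stood at 119 TPM in NN in the authors' deposited table (q = 0.98).

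**Figure D3:**
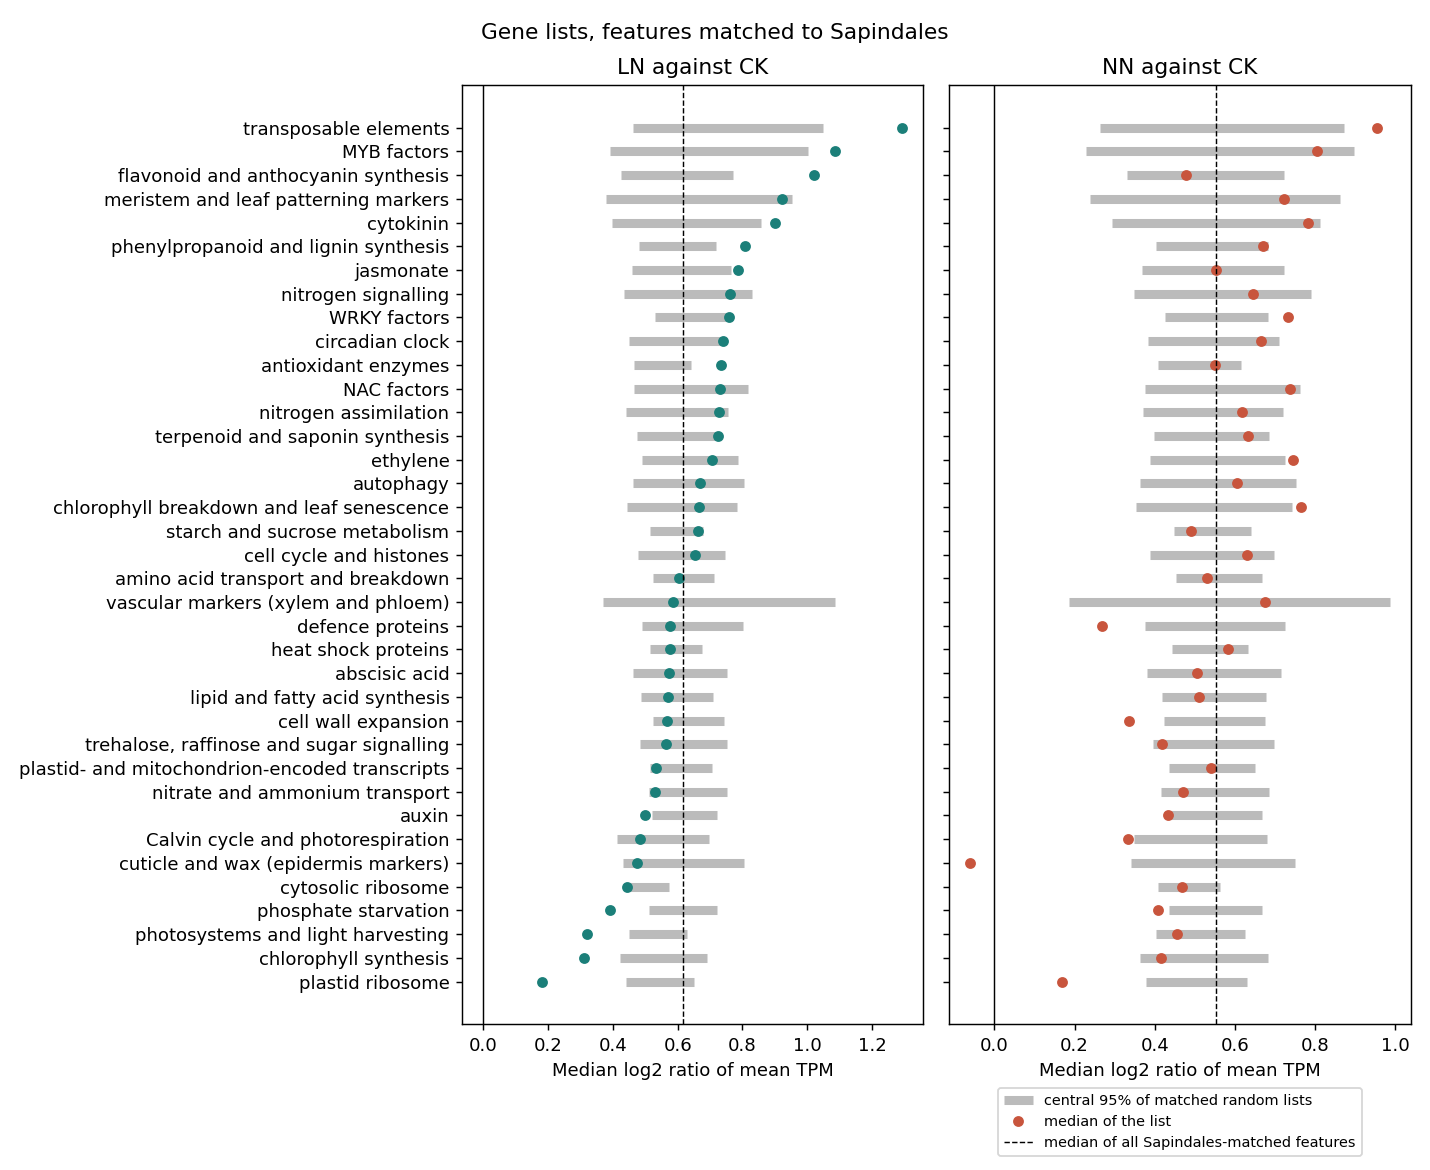
Median log2 ratio of mean TPM (x axis) of the Sapindales-matched members of each fixed gene list (y axis), for LN (left) and NN (right) over CK; grey bars span the central 95% of 10000 random lists matched on mean expression and the dashed line is the median of all Sapindales-matched features. Flavonoid and anthocyanin synthesis stood at 1.02 in LN and 0.48 in NN, and cuticle and wax at 0.47 and -0.06.

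By fold change, the highest risen genes in NN were a pyrophosphate-energized proton pump 2 (log2 fold change 5.73), a putative disease resistance protein RGA3 (3.85), a legume-matched mitogen-activated protein kinase kinase kinase 1 (3.40), a proton pump 3 (3.15) and oligopeptide transporter 7 in the authors' deposited table. The lowest were feruloyl CoA ortho-hydroxylase 1 at -7.00, the WAT1-related protein at -5.75, a second feature of feruloyl CoA ortho-hydroxylase 2 (TRINITY_DN75758_c2_g1) at -4.94, the agglutinin at -4.71 and the cysteine proteinase at -4.60 in the authors' deposited table. None of these matched Sapindales: the cysteine proteinase matched Arabidopsis and its relatives, the others other flowering plants. Both hydroxylase features share an assembly component with TRINITY_DN75758_c2_g5, which had a log2 fold change of 1.96 in NN in the authors' deposited table (q = 0.98). In total 90 features rose and 27 fell at the authors' q, 77 and 21 did so among plant matches, and 31 and 8 among Sapindales matches. The authors' calls at an unadjusted p numbered 2476 higher and 3007 lower in the deposited table.

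LN and NN were not compared by the authors' tables, so only ratios of their group means are given, without a test. Across Sapindales-matched features of at least 1 TPM the median log2 ratio of NN over LN was -0.07. Flavonoid and anthocyanin synthesis had a median of -0.49 (random lists -0.21 to 0.07), cuticle and wax -0.59 (-0.24 to 0.08), cell wall expansion -0.25 (-0.18 to 0.01), defence proteins -0.28 (-0.22 to 0.04), jasmonate -0.23 (-0.20 to 0.06) and the Calvin cycle and photorespiration -0.18 (-0.16 to 0.07). Photosystems and light harvesting had 0.12 (-0.10 to 0.05), heat shock proteins 0.11 (-0.13 to 0.01), cell cycle and histones 0.08 (-0.19 to 0.04), phosphate starvation 0.07 (-0.15 to 0.02) and plastid- and mitochondrion-encoded transcripts 0.04 (-0.15 to 0.01). Over all plant matches 2 of these 6 low lists, cell wall expansion and jasmonate, and 4 of the 5 high lists kept their place. The Calvin cycle list then lay above random lists, at 0.20. The cysteine proteinase stood at 628 TPM in LN and 21.3 in NN, and the agglutinin at 51.9 and 0.985 TPM in the authors' deposited table. Glutamate dehydrogenase 1 stood at 30.2 TPM in LN and 57.5 in NN, and leucoanthocyanidin reductase at 15.5 and 8.26 TPM in the authors' deposited table.

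**Figure D4:**
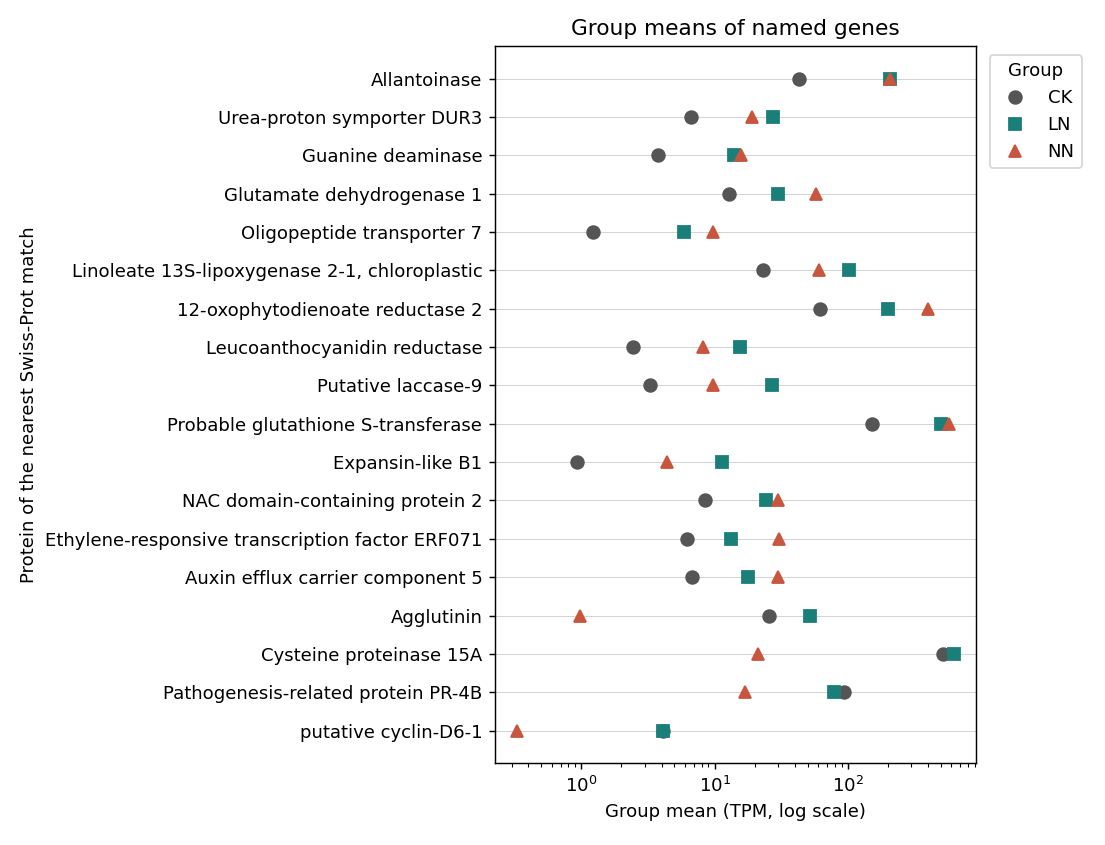
Group means of named genes (x axis, TPM on a log scale) in CK, LN and NN, 1 row per gene (y axis), from the authors' tables without error bars because these give group means only. Allantoinase stood at 42.8 TPM in CK, 208 in LN and 207 in NN, and the cysteine proteinase at 514, 628 and 21.3.

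The LN and NN calls overlapped. At the authors' q, 13 Sapindales-matched features rose in both LN and NN, of 75 and 31 among the 12437 features, where independent lists would share 0.19, and 1 fell in both, of 5 and 8. Allantoinase and the glutathione S-transferase were among those that rose in both. At an unadjusted p below 0.05, 753 rose in both, of 1753 and 1515, where independent lists would share 214, and 10 fell in both, of 30 and 93, where independent lists would share 0.22. A shared control alone gives overlap: in a simulation of unchanged groups against the same CK libraries, risen lists of 333 and 342 shared 65 where independent lists would share 9.16, and fallen lists of 334 and 306 shared 61 where these would share 8.22. List sizes differ, so these overlaps do not measure its part. Of the features, 73.6% lay on the same side of the median shift in LN and NN, and 66.1% did so in the simulation. The 3 CK libraries could not be split here, so how much of the overlap comes from them stays open.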

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

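The tests of the fallen calls, of the dilution and of other organisms among the NN genes were chosen after the results were seen; those of the most abundant features and of near-identical copies were set down before.

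The 703 features matched to the bacterium Sphingomonas summed to 6891 TPM in CK, 11359 in LN and 11787 in NN, which lies above the control level. These matches are in no gene list of the report, though the authors' comparisons test them and the totals of changed features count them. The difference lay in 1 feature, TRINITY_DN76104_c3_g3, with 4803, 9986 and 9850 TPM in the authors' deposited table (q = 0.19 and 0.98), whose protein match is a plant chlorophyll a-b binding protein. The other 702 features summed to 2088 TPM in CK, 1373 in LN and 1937 in NN, below CK in both.

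The authors' calls in LN fell more often than they rose, 5636 against 2475. Of the Sapindales-matched features past q 7.14% fell, but this cannot decide on lower expression of yellowhorn genes at low nitrogen. In LN 94.4% of Sapindales-matched features lay above CK, a shift whose cause stays open below, so few could be called fallen. The same shift held down the share of fallen calls among Sapindales matches, 2.16%, so this share cannot decide on reads from other organisms either. Reads from other organisms, more of them in CK, may still account for the excess: 99.9% of the calls among rodent matches fell, and these made up 3593 of the 5636 lower calls. Where these reads came from stays open, because the tables do not show which CK libraries held them.

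Sapindales-matched features lay above CK as a whole, by a median of 0.62 in LN and 0.55 in NN. A few features taking most of the TPM is argued against: without the 100 most abundant features the median shift was 0.53 in LN and 0.44 in NN. Dilution by other organisms' reads cannot be told apart from other causes: counting Arabidopsis, legume, grass and other green plant matches among them, a share of 36.2% in CK, 22.3% in LN and 23.6% in NN predicts a shift of 0.28 and 0.26. Some of those plant matches may be leaf genes. The share leaves out matches to organisms that were not classified, which held 10.9% in CK, 8.47% in LN and 7.45% in NN. Their median log2 ratio in LN was -1.14, and counting them would raise the predicted shift. That shift was not computed with them, so how much of the observed shift dilution predicts depends on leaving them out. Non-plant matches alone, 18.0% in CK, 8.09% in LN and 9.03% in NN, predict 0.16 and 0.15. A general rise of leaf transcripts at lower nitrogen was not tested.

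In NN, 19 plant-matched genes above the floor fell past q, with a median log2 ratio of -3.64. Reads from other organisms that were fewer in LN than in CK, as rodent matches were, are argued against. The median log2 ratio of LN over CK of these genes was -0.057 (quartiles -0.34 and 0.21), while rodent matches had -1.70. Reads from an organism about as frequent in LN as in CK but rarer in NN could not be seen this way. For 14 of them that share an assembly component with other features, the component sums had a median of -1.62, which passes the bound of -1 set beforehand against reads moving between near-identical copies. The quartiles of these sums were -2.55 and 0.10, with 6 sums above -0.5, so after the result was seen the bound was also required of the upper quartile, and this explanation stays open for those genes. The absence of nitrogen, or differences between the plants sampled, may also cause these falls and were not tested.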

How the results depend on the processing

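No paired analysis was possible because the tables give only group means; for the same reason other normalizations, count filters, limma, left-out libraries, the replicate block and gene set tests were not run, and depth is unknown. All settings below except the plant matches and the 2-fold minimum, and for the shared genes the authors' calls, were chosen after seeing the data. Of the 320 features changed in LN (48.4% fallen), plant matches kept 152 (6.58% fallen), Sapindales matches 84 (7.14%) and Sapindales with other flowering plants 140 (5.71%), by construction fewer features. The authors' calls were 8111 (69.5%), p adjusted over all features gave 46 (21.7%) and over features of at least 1 TPM 155. Of the 117 changed in NN (23.1% fallen), Sapindales matches were 39, the authors' calls 5483 (54.8%) and p adjusted over features of at least 1 TPM gave 203. Of the changed features, 28 were shared by LN and NN in 1 direction, and 2861 by the authors' calls. In NN, 11 lists lay outside the range of random lists, 19 with other flowering plants included and 18 over all plant matches. A minimum of 2-fold, the floor and the Sapindales median moved no count by over 1.5 times. With a pseudocount of 1, TPM summed per Swiss-Prot entry, other flowering plants included and all plant matches, 9, 8, 7 and 5 of the 9 lists above random lists in LN stayed so, and 1, 0, 4 and 2 of the 4 in NN. Of the 6 below in LN 5, 5, 6 and 4 did, and of the 7 in NN 5, 5, 6 and 6. Of the 22 lists within random lists in LN, 3, 2, 3 and 1 then lay above and 1, 3, 5 and 9 below, and of the 26 in NN 4, 1, 3 and 3 above and 2, 2, 6 and 7 below. Over all plant matches 15 list medians changed sign in LN and 13 in NN. Among lists outside the range of random lists, these were in LN photosystems (-0.72; -0.54 with Sapindales and other flowering plants), phenylpropanoids (-0.041), auxin (-0.042), antioxidants (-0.41), cytosolic ribosome (-0.64) and plastid ribosome (-0.24). In NN they were the Calvin cycle (-0.21), auxin (-0.076), defence (-0.27), plastid ribosome (-0.14) and cell wall expansion (-0.30); the cause was not tested.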

Other observations

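A group chosen after seeing the data, purine and ureide breakdown with urea uptake, had 4 of its 27 plant-matched features risen and none fallen in LN at the authors' q, and 2 risen in NN. Besides allantoinase, the urea-proton symporter DUR3 rose from 6.71 TPM in CK to 27.6 in LN and stood at 19.2 in NN in the authors' deposited table (q = 0.0010 and 0.11). Guanine deaminase, which removes ammonium from guanine, rose from 3.77 to 15.7 TPM in NN and stood at 14.0 in LN in the authors' deposited table (q = 0.036 and 0.068). Members were seen to rise before it was drawn up, so no comparison with random lists is given.

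Transposable element features, a list fixed before the data were examined, had 5 of 256 risen in LN and 1 in NN at the authors' q, of which 1 and 0 matched Sapindales, and 6 and 17 adjusted over the list alone. A Ty3-type polyprotein went from 1.31 TPM in CK to 6.79 in LN and 8.17 in NN in the authors' deposited table (q = 0.0028 and 0.015). The 22 Sapindales-matched members had medians of 1.29 in LN (random lists 0.46 to 1.05) and 0.95 in NN (0.26 to 0.87). These features are of low abundance: with a pseudocount of 1 the medians were 0.73 and 0.34, and with TPM summed per Swiss-Prot entry 1.27 and 0.68, and under both settings NN lay within random lists. Phosphate starvation genes lay low in both, with medians of 0.39 in LN (0.51 to 0.72) and 0.41 in NN (0.43 to 0.67) over 50 members, and no member past q. Over all plant matches the list lay within random lists in LN (0.16 against 0.03 to 0.47) and NN (0.25 against 0.01 to 0.43). In NN it also did so with other flowering plants included (0.41 against 0.40 to 0.63).

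Single members passed the authors' q in other fixed lists. In LN these were WRKY transcription factor 6 of the senescence list, from 0.106 to 1.64 TPM, ABC transporter G family member 11 of the cuticle list, which exports wax and cutin precursors, from 0.513 to 3.22 TPM, and a chitinase of the defence list, from 0.317 to 2.06 TPM in the authors' deposited table. A feature described as uncharacterized mitochondrial protein AtMg00810 rose from 0.499 to 1.92 TPM in the authors' deposited table (q = 0.048). Its description placed it in the plastid- and mitochondrion-encoded list, and whether an organelle encodes it was not tested. That list had no member past the threshold when adjusted over the list alone. In NN a regulatory beta-2 subunit of an SNF1-related kinase, placed in the abscisic acid list by its description, rose from 0.546 to 3.04 TPM in the authors' deposited table. The MYB list had 1 risen member in LN, Myb4, matched to other flowering plants, from 0.661 to 3.95 TPM in the authors' deposited table. The median of its 12 Sapindales-matched members was 1.08 (random lists 0.39 to 1.00), while the 31 members matched to other flowering plants had 0.59. Cytokinin genes had a median of 0.90 in LN (0.40 to 0.86) with no member past q. Lists of the Calvin cycle, chlorophyll synthesis, autophagy, starch and sucrose, vascular and meristem markers, lipids, trehalose and raffinose, and the circadian clock had no member past q in LN or NN.

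Some features differed at least 4-fold in mean at 5 TPM or more yet had a p of exactly 1 in the authors' deposited tables, 143 in LN and 131 in NN.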
